A study of Homo sapiens with 3 samples.

How the data were processed

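The series profiled trimethylation of lysine 9 on histone H3 (H3K9me3) by chromatin immunoprecipitation and sequencing in Jurkat cells, an established line from a T cell acute lymphoblastic leukaemia. Cells were kept without serum for 90 min and were then given the chemokine CXCL12 at 100 ng/ml for 15 min or left untreated. Per the labels' protocols, fixation took 15 min in 1% formaldehyde, and 30 µg of chromatin went into each immunoprecipitation. The samples were grouped by their treatment label into CXCL12, control and input, with 1 library in each. The input library was not analysed here, so no background signal is set beside the values.

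The deposited regions come as a list per immunoprecipitated library, with position, length, signal and annotated genes for each region. BWA 0.7.12, SICER 1.1 and the build hg19 are named per the submitters' processing notes, and the settings are not given in the sources used here. BWA aligns reads and SICER calls broad regions by joining enriched windows, and in the deposited lists both starts and lengths move in steps of 200 bp. The signal values deposited by the authors are a mean over the bins of a region and the value of its highest bin, per the file headers. A region's mean signal multiplied by its number of bins was whole, within 0.001%, in 100% of regions, and the bins measured 32.9 bp at the median. Whether the signal was scaled between libraries, thinned to a common depth or corrected with the input is not given in the sources used here. The number of reads is not given either, so the depth of each library is unknown and no counting interval was placed on a signal value. Over the same bins, a fixed offset in depth between the libraries would move all signal ratios together. It would also lengthen the regions called in the deeper library. A mean is taken over the called bins, so its ratio could then move differently from locus to locus. Coordinates are given as deposited, in hg19. Whether they count from 0 or 1 is not given in the sources used here, and region lengths include both end positions.

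Regions of either library that shared at least 1 bp were chained into loci. A locus was shared when it held regions of both libraries. The mean signal of a locus was taken over all its bins in each library, and the ratio of CXCL12 to control was expressed as log2 with no pseudocount. Ratios exist only for shared loci, because no signal is listed for a library in which nothing was called. With 1 library per group there is no replicate spread, so no p-value was computed, and loci at least 2-fold apart are described by that rule of size alone. Any difference between the libraries can hold both the treatment and the variation between separate preparations. Shares are given with exact (Clopper-Pearson) 95% binomial intervals and medians with exact order-statistic 95% intervals. These intervals cover the spread over regions in these libraries and not the variation between cultures. As a background for the overlap, the control regions were shifted along each chromosome by a random distance 100 times.

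The comparisons, the 2-fold rule, the rule for named genes and 12 gene lists were fixed before the data were examined. The lists were zinc finger genes, clustered protocadherins, olfactory receptors, keratin-associated proteins, chemokines and chemokine receptors, T cell genes, B cell and myeloid genes, neuronal adhesion and synapse genes, the H3K9 methylation machinery, nuclear envelope genes, adhesion and migration genes, and imprinted genes. The median log2 ratio of each list was placed among 10000 random sets of as many shared loci, matched on deciles of mean signal. Its percentile describes these libraries and is not a p-value. Loci were named where they carried a gene and lay among the 12 largest or 12 smallest ratios of loci at or above the median signal, or among the 5 highest signals of shared loci. The 5 highest signals of the gene-carrying loci called in a single library and up to 4 highest-signal members per list were also named. CXCR4, CXCL12, LMNA, SUV39H1, SETDB1 and EHMT2 were looked up in any case. Chromosome Y and unplaced contigs were left out of the naming. Gene names are those of the deposited lists, which give the position of a region as in, upstream or downstream of a gene but not the exon or intron. A locus named by a gene can therefore lie beside that gene. Of 7655 symbols, 6592 (86.1%) matched a current symbol or a single synonym in a RefSeq gene table, which served only to count protein-coding genes. A further 52 gene entries had been turned into dates by a spreadsheet and were left out.

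The alternatives planned at the outset were a 1.5-fold rule, ratios centred on their median, loci or regions at or above the median signal, the highest bin in place of the mean, a pseudocount of 1, a stricter overlap, weighting by length, random lists matched on length, the nearest gene alone and shares of covered length. Chosen after seeing the data were loci with 1 region per library whose lengths lie within 1.2-fold of each other, the summed signal, and regions of at least 5 kb. The scripts were tested on simulated data made from the 21541 shared loci. In these, 200 of 200 loci planted at a log2 ratio of 1.5 in either direction were recovered and 0 unchanged loci passed the 2-fold rule. Of the loci planted in a single library, 2000 of 2000 were found. Simulated loci had equal lengths in both libraries, and the unchanged ones spread less in ratio than the data (SD 0.27). The simulation therefore checks the code and not how often the 2-fold rule passes unchanged loci in the data. The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.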

Results

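H3K9me3 marks constitutive heterochromatin and silenced gene families, and the series addressed whether a short exposure to CXCL12 alters its distribution in leukaemic T cells. CXCL12, also called SDF, is a chemoattractant that acts through the receptor CXCR4. H3K9me3 regions were available from 1 CXCL12-treated and 1 untreated control library of Jurkat cells, so no difference below has a replicate check. The depth of the libraries is unknown, and signal is the authors' value per bin of a region.

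H3K9me3 lay over much the same parts of the genome in both conditions, with the longest domains over zinc finger gene clusters of chromosome 19 and slightly more DNA called after CXCL12. The longest control region spanned 386.8 kb at chromosome 19, 58429000 to 58815799, across ZNF417, ZNF418 and ZNF256, which belong to the large family of zinc finger transcription factors. The longest CXCL12 region spanned 391.8 kb at chromosome 19, 52800800 to 53192599, across ZNF766, ZNF480 and ZNF610. The control library held 26938 regions over 144 Mb and the CXCL12 library 27178 regions over 154 Mb, which is 240 regions and 10.0 Mb more, or 6.94% more covered length. The median region measured 4000 bp (quartiles 2600 and 6200 bp) in control and 4200 bp (2800 and 6600 bp) after CXCL12. The median of the mean signal per region was 5.06 (quartiles 4.02 and 6.61) and 5.10 (4.08 and 6.67), respectively. Summed over all bins the signal was 8.11% higher after CXCL12, while the mean over all bins was 6.75 in control and 6.83 after CXCL12. Regions of at least 20 kb numbered 502 in control and 550 after CXCL12.

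Of the chromosomes listed, chromosome 19 had the most DNA in H3K9me3 regions, with 12.5 Mb in control and 12.7 Mb after CXCL12, although it held only 3.10% of the control regions. Its median control region measured 7000 bp, against 2600 bp on chromosome X. More DNA was called after CXCL12 on each of the 23 chromosomes listed, from a ratio of 1.02 on chromosome 19 to 1.1 on chromosome 3. The median log2 signal ratio was above 0 on all 23 before centring, from 0.004 on chromosome X (interval −0.017 to 0.029) and 0.03 on chromosome 12 to 0.06 on chromosome 6. By the highest bin the median was lowest on chromosomes 5 and 16, at 0, and it was 0.09 on chromosome X.

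**Figure D1:**
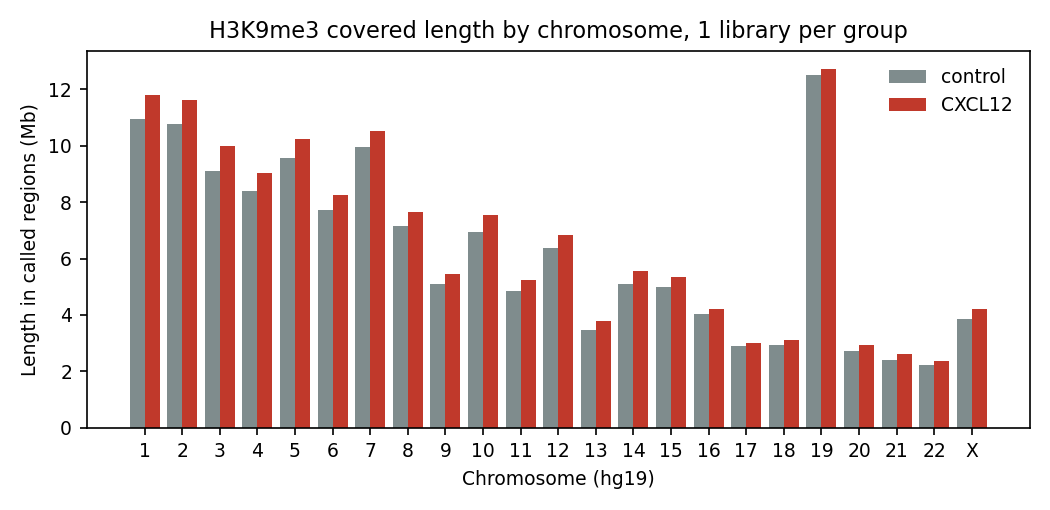
Length in called H3K9me3 regions (Mb) on chromosomes 1 to 22 and X, with a grey bar for the control library and a red bar for the CXCL12 library, 1 library each. The red bar is the taller on all 23 chromosomes, and chromosome 19 has the tallest pair, at 12.5 and 12.7 Mb.

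Gene bodies, gene flanks and gene-free DNA took up near-equal shares of the regions in both libraries. A gene body was annotated at 33.6% of control regions (interval 33.0 to 34.1%) and 33.6% of CXCL12 regions (33.0 to 34.1%). No gene was annotated at 54.7% of control regions and 55.0% of CXCL12 regions, and a promoter at 8.29% and 8.10%. CpG islands lay in 4.34% of control regions (4.10 to 4.59%) and 4.12% of CXCL12 regions (3.88 to 4.36%). Promoter-bearing regions were long, so that they made up 15.5% of the covered length in control and 15.3% after CXCL12.

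The H3K9me3 landscapes of stimulated and unstimulated cells were then compared by overlap. Most regions occurred in both: 86.7% of control regions (86.3 to 87.1%) lay in a locus shared with CXCL12, and 84.2% of CXCL12 regions (83.8 to 84.7%) lay in a locus shared with control. After random shifts of the control regions, a mean of 8.98% and at most 9.67% of CXCL12 regions touched one. Of 29404 loci, 21541 were shared, 3580 were called in control only and 4283 after CXCL12 only. The base pairs called in both libraries came to 119.7 Mb, which is 82.9% of the control length and 77.6% of the CXCL12 length. Loci called in a single library were short and weak. Their median length was 2400 bp in control and 2600 bp after CXCL12, and their median signal was 3.96 and 3.86, against 5.31 and 5.42 for the regions of shared loci. Within shared loci, 15.0 Mb were called in control only and 22.3 Mb after CXCL12 only.

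Among the loci seen in a single library that carry a gene, the highest signal lay at a repeat-rich chromosome end in control and upstream of MTIF3 after CXCL12. Loci without a gene were not ranked. In control only, a 10000 bp region at DUX4C and FRG2 near the end of the long arm of chromosome 4 (190933000 to 190942999) had a mean signal of 21.1. EPPK1, which encodes the cytoskeletal linker epiplakin, carried a control-only region at chromosome 8, 144937800 to 144941799, with a mean of 12.7 and a highest bin of 89. The other control-only loci named were at LOC100507153 (13.4; chromosome 3, 197367800 to 197368599), ANKRD30B (11.4) and MIR3118-2 (10.9). After CXCL12 only, the highest mean signal was 22.5 upstream of MTIF3, a mitochondrial translation initiation factor, over 800 bp at chromosome 13, 28033400 to 28034199. Regions inside RYR2, the cardiac ryanodine receptor (12.6), the immunoglobulin heavy chain locus IGH@ (12.1), LOC100132653 (12) and the calcium channel gene CACNA1B followed. The CACNA1B region had a signal of 11.9 over 11000 bp at chromosome 9, 141008600 to 141019599, and the nearest control region was 25.8 kb away. The nearest control region was 107 kb from the RYR2 locus and 109.6 kb from the IGH@ locus, but only 8.40 kb from the MTIF3 locus and 2.20 kb from the LOC100132653 locus. From the DUX4C locus the nearest CXCL12 region was 2.80 kb away, and from the EPPK1 locus 4.20 kb. All 5 control-only loci named lay close to one, from 1.00 kb at LOC100507153 to 8.40 kb at MIR3118-2. This contrast between the named loci did not extend to all loci of a single library. Within 5 kb of a region of the other library lay 27.0% of control-only and 29.0% of CXCL12-only loci, with median distances of 16.9 and 14.8 kb. DUX4C and FRG2 have near-identical copies elsewhere in the genome, so the assignment of their reads is uncertain. The other single-library loci were not examined for copies, and the same limit may hold for them.

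The signal at shared loci was then compared. H3K9me3 signal was close to equal in both libraries: the median log2 ratio of CXCL12 to control was 0.04 (0.036 to 0.044) with quartiles of −0.12 and 0.20 and an SD of 0.27 over 21541 loci. At least 2-fold differences occurred at 25 loci higher after CXCL12, led among the named loci by FUT8, and at 38 loci lower, led by SLC27A2. At 9488 loci with 1 region per library and lengths within 1.2-fold of each other, an alternative chosen after seeing the data, 0 were 2-fold higher and 0 were 2-fold lower by mean signal, with a median of 0.062, while 53 were 2-fold higher and 14 lower by the highest bin. Called length itself follows the signal, so this selection removes loci in part by the difference it looks for. By the highest bin 150 of all shared loci were 2-fold higher and 60 lower, so the balance of the directions depends on the measure. The summed signal, which follows the called length (1195 loci at least 2-fold longer after CXCL12 and 614 shorter), was 2-fold higher at 612 loci and lower at 215. Across shared loci the ratio of mean signal fell as the ratio of length rose (Spearman rho −0.617), a relation partly built into a mean over called bins.

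**Figure D2:**
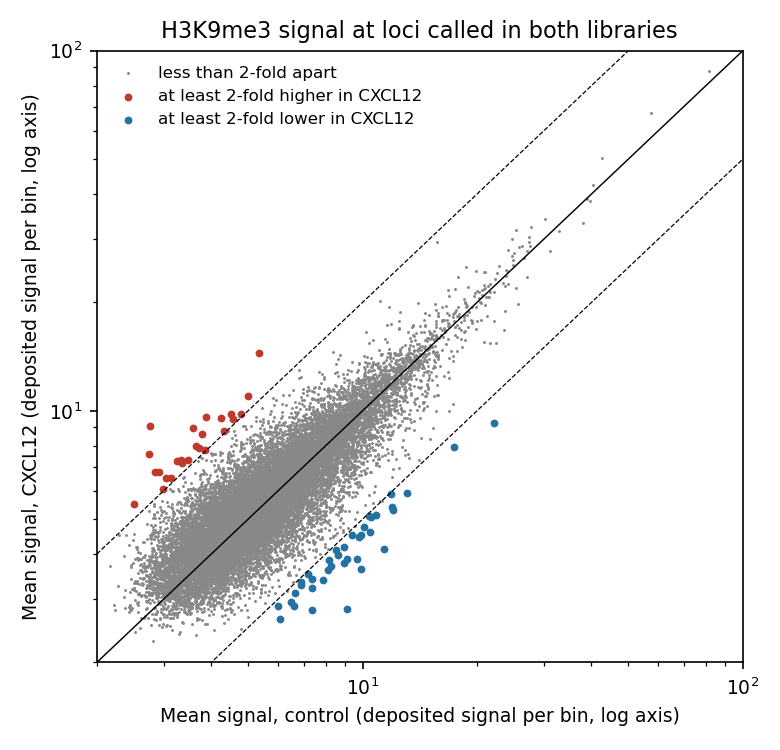
Mean H3K9me3 signal per bin of each of the 21541 shared loci in the control library (horizontal) and in the CXCL12 library (vertical), both on log axes, with 1 point per locus. The solid line marks equal signal and the dashed lines a 2-fold difference, which 25 loci exceed upwards (red) and 38 downwards (blue).

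Among shared loci at or above the median signal that carry a gene, the largest ratios belonged to genes of varied function. FUT8, the enzyme that adds core fucose to glycoproteins, had a mean signal of 2.77 in control and 9.08 after CXCL12 at chromosome 14, 66159200 to 66160999, inside the gene (log2 ratio 1.71). C1orf125 followed with 5.35 and 14.5 (1.44), and GABRG3, a subunit of the GABA type A receptor, with 3.78 and 8.64 (1.19). Near-2-fold or larger ratios were also found at LOC100287759 (1.14), ZNF596 (1.13), the mitochondrial carrier gene SLC25A24 (1.07), the cornified envelope gene LCE3C (1.05), CCDC46 (1.03), C11orf65 (1.02), LOC100507153 (0.96) and a pair of loci within EDA (both 0.99), the gene of the signalling ligand ectodysplasin A. In 12 of these 12 loci the region was shorter after CXCL12, as at FUT8 with 1800 bp in control and 400 bp after CXCL12. The log2 ratio of the highest bin lay between 0 and 0.93 and was 2-fold in 0 of the 12. The summed signal, which follows the called length, had a log2 ratio below 0 at 10 of the 12, among them C1orf125 (−0.48) and SLC25A24 (−0.87). The LOC100507153 locus, at chromosome 3, 197369600 to 197370999, lies beside the control-only region named above. The LOC100287759 locus, at chromosome 9, 66461400 to 66462399, lies beside one of the strongest loci named below, which had a log2 ratio of −0.05.

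The smallest ratios of the same set of gene-carrying loci were likewise spread over unrelated genes. The locus upstream of SLC27A2, which encodes a fatty acid transporter and acyl-CoA synthetase, had a mean signal of 11.4 in control and 4.14 after CXCL12 at chromosome 15, 50462800 to 50466199 (log2 ratio −1.46). NUBPL, an assembly factor of mitochondrial complex I, had 9.88 and 3.63 at chromosome 14, 32333600 to 32337199, downstream of the gene (−1.44). In the protocadherin alpha cluster a locus at chromosome 5, 140226000 to 140231599, had 22.2 and 9.22 (−1.27), with highest bins of 41 and 39. The remainder were at ZNF254 (−1.24), LOC100507291 (−1.22), the potassium channel gene KCND2 (−1.15), MIR552 (−1.14), SLFN5 (−1.13), the liver glycogen synthase gene GYS2 (−1.13), UACA (−1.12), NNT (−1.08) and VPS8 (−0.999). The region was longer after CXCL12 in 12 of these 12 loci, from 1000 to 3400 bp at SLC27A2. The highest bin was also at least 2-fold lower in 2 of them, NUBPL (23 and 9) and ZNF254 (16 and 8), and at NNT it was higher after CXCL12 (16 and 18). The log2 ratio of the summed signal was above 0 at 8 of the 12, among them GYS2 (1.08), LOC100507291 (0.96) and SLC27A2 (0.29).

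**Figure D3:**
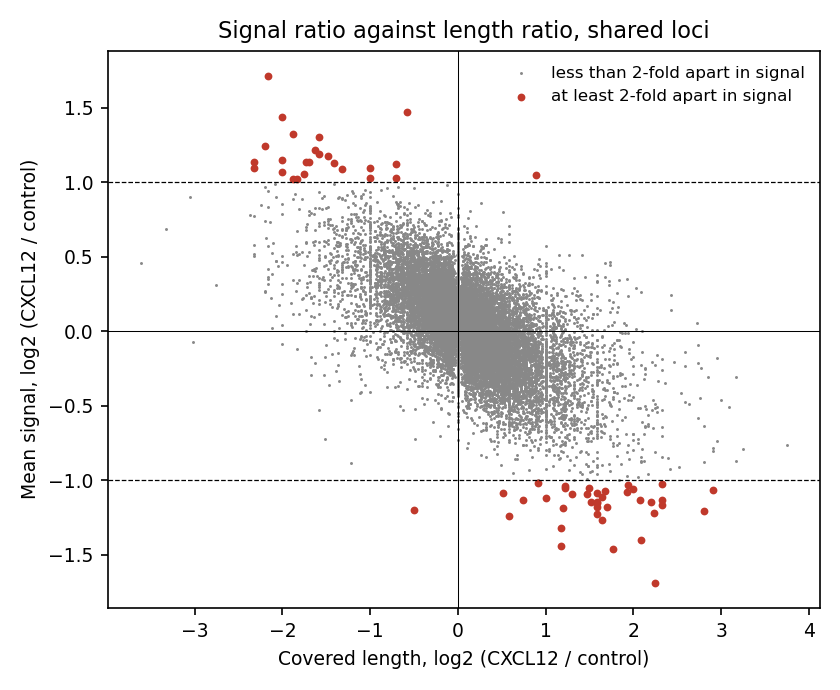
Log2 ratio of mean signal (vertical) against log2 ratio of covered length (horizontal), CXCL12 over control, for the 21541 shared loci, with 1 point per locus and dashed lines at a 2-fold signal difference. Of the 63 loci at least 2-fold apart (red), 61 have the shorter region in the library with the higher mean signal.

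Among shared loci that carry a gene, the 5 strongest H3K9me3 signals lay at LOC100507651, KATNAL2, SNRPN, CDC27 and LOC100287759. Upstream of LOC100507651 on chromosome 8 (58122000 to 58123399) the mean signal was 57.4 in control and 67.1 after CXCL12, and at KATNAL2 with the TCEB3 copies on chromosome 18 (44553200 to 44554399) it was 42.7 and 50.4. Over the SNORD115 small nucleolar RNA repeats within SNRPN, at chromosome 15, 25402200 to 25503399, it was 40.4 and 42.3 across 100.2 and 101.2 kb. At CDC27, a subunit of the anaphase-promoting complex, it was 39.8 and 38.3. At LOC100287759, at chromosome 9, 66454600 to 66460399, it was 32.8 and 31.6. Log2 ratios at these 5 loci ran from −0.05 to 0.24. Reads from the SNORD115 repeats and the TCEB3 copies can fall on any copy, so these levels are uncertain. Whether the other loci named here have copies elsewhere was not examined, so their levels may be uncertain too.

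Zinc finger genes, many of which lie under H3K9me3, had a slightly higher median log2 ratio of mean signal than all shared loci (0.063 against 0.040). By the highest bin it was not higher (0.063 against 0.074). A region was present at 386 of 561 protein-coding members (68.8%, interval 64.8 to 72.6%), against 6009 of 20052 protein-coding genes in all (30.0%). Neighbouring members share loci, up to 11 in the domain of ZNF417, ZNF418 and ZNF256, so this interval may be too narrow. Of 472 shared loci, 337 had a log2 ratio above 0 and 135 below, before centring. Over all 21541 shared loci, 12283 were above 0 and 9251 below. The median of the zinc finger loci was 0.063 (0.048 to 0.072). It lay at percentile 99.2 of random lists, whose central 95% ran from 0.010 to 0.057. The position was lost with random lists matched on length (percentile 93.7), with the highest bin (34.6) and at loci of matched length (91.4). ZNF7 had a mean signal of 22.1 in control and 21.4 after CXCL12. The 386.8 kb domain that holds ZNF135, ZNF256 and ZNF274 had 20.2 and 20.5.

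Other tandem gene families were under H3K9me3 to different degrees, where 30.0% of all protein-coding genes had a region. Clustered protocadherins, neuronal cell adhesion molecules, had a region at 48 of 53 members. Members share regions, and the 28 shared loci carried 44 of these genes. These loci had a median log2 ratio of −0.05 (−0.10 to 0.06) at percentile 4.80, inside the central range, and −0.03 at loci of matched length. The highest bin placed them outside that range, at percentile 2.40. Over the domain at PCDHB15 the mean signal was 11.4 and 12, and at PCDHB14 it was 11 and 11.5. PCDHGA1 and PCDHGA2 lay over the same loci, with 11 and 11.4. All 4 genes include the domain at chromosome 5, 140609800 to 140715399, so their values are not separate. The highest bin of that domain went the other way, with 86 in control and 80 after CXCL12. Olfactory receptors had a region at 85 of 390 members, with a median of 0.03 over 74 shared loci (percentile 41.1), a little below the median over all shared loci, and 0.06 at loci of matched length. They had 5 loci in control only and 20 after CXCL12 only, where the protocadherins had 5 and 1 and all loci together 3580 and 4283. OR10H3 had 12.7 and 15.0, OR10H4 10.9 and 10.7, OR2M7 8.26 and 9.41, and OR2B6 8.66 and 8.99, the loci of OR2M7 and OR2B6 lying downstream. The highest bin went the other way at OR10H4 (49 and 62), OR2M7 (24 and 20) and OR2B6 (27 and 25). Keratin-associated proteins, structural proteins of hair, had a region at 25 of 94 members and a median of −0.03 over 11 shared loci (percentile 19.1), which was 0.15 by the highest bin. At the locus of KRTAP10-4, KRTAP10-5 and KRTAP10-6 the signal was 14.4 in both libraries, and at KRTAP10-7 it was 10.7 and 10.2, with highest bins of 40 and 47.

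A part of the lineage genes had an H3K9me3 region in or beside the gene, and no lineage list stood apart from random lists. The share with a region was 37.5% for T cell genes (21.1 to 56.3%) and 36.0% for B cell and myeloid genes (18.0 to 57.5%). Each interval held the 30.0% of all protein-coding genes. T cell genes had a region at 12 of 32 members and a median log2 ratio of 0.10 over 19 shared loci (percentile 83.3), which was 0.018 (percentile 23.7) at loci of matched length. The surface receptor gene CD2 had the highest signal of the list, 18.7 in control and 20.3 after CXCL12 over a pair of loci between 117282600 and 117320999 of chromosome 1. IL7R, the interleukin 7 receptor, had a mean of 13.8 in both libraries at a locus upstream of the gene, with highest bins of 51 in control and 34 after CXCL12. The co-receptor gene CD8A had 7.87 and 9.34, and the recombinase gene RAG2 8.57 and 7.90 downstream of the gene. B cell and myeloid genes had a region at 9 of 25 members and a median of 0.06 over 8 shared loci (percentile 60.3), which was 0.28 by the highest bin (percentile 95.2). PAX5, the B cell commitment factor, had 10.4 and 11.1 within the gene at chromosome 9, 36989000 to 36993799. CD14 had 8.91 and 9.44 and CEBPA 6.63 and 7.58, each downstream of the gene, and BLK had 5.49 and 5.39.

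Chemokine, adhesion and migration genes, the groups closest to the stimulus, also stayed inside the random range. The share with a region was 30.9% for chemokines and their receptors (20.2 to 43.3%) and 34.2% for adhesion and migration genes (19.6 to 51.4%). All protein-coding genes had 30.0%. Chemokines and their receptors had a region at 21 of 68 members and a median of 0.07 over 18 shared loci (percentile 69.8), which was 0.03 by the highest bin (37.2). CCR4, a receptor of skin-homing T cells, had a signal of 15.3 in control and 14.6 after CXCL12 downstream of the gene at chromosome 3, 33005200 to 33010399, with highest bins of 39 and 52. CCL25 had 11.2 and 11.7 and CCL24 10.6 and 10.5, each downstream of the gene, and the B cell attractant gene CXCL13 had 9.49 and 8.44. Adhesion and migration genes had a region at 13 of 38 members and a median of 0.07 over 24 shared loci (percentile 72.6), which was 0.14 at loci of matched length (87.3) and 0.03 with the nearest gene alone (44.4). DOCK2, an activator of Rac in lymphocytes, had 8.65 and 10.2 within the gene at chromosome 5, 169272200 to 169281599. WASF1 had 6.99 and 8.96, VAV2 8.38 and 6.83, and JAK2 6.86 and 6.73. The highest bin went the other way at DOCK2 (29 and 28), VAV2 (32 and 36) and JAK2 (35 and 60). No region was called at CXCR4 or at CXCL12 in either library.

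Genes of H3K9 methylation and of the nuclear envelope were covered in part, at 40.7% (22.4 to 61.2%) and 16.7% (3.58 to 41.4%) of members. Each interval held the 30.0% of all protein-coding genes. The H3K9 methylation machinery had a region at 11 of 27 members and a median of 0.09 over 32 shared loci (percentile 81.9), which was 0.20 by the highest bin (percentile 96.5). The demethylase gene KDM4B had 10.6 in control and 10.4 after CXCL12, the methyltransferase gene EHMT1 10.0 and 10.9, the demethylase gene KDM3A 7.35 and 8.09, and ATF7IP, a partner of SETDB1, 6.79 and 8.11. Within the methyltransferase gene SETDB1, a region at chromosome 1, 150900600 to 150904799, had 4.70 and 4.31 (log2 ratio −0.12) over 4200 and 2000 bp. Neither library had a region at SUV39H1, EHMT2 or LMNA. Nuclear envelope genes had a region at 3 of 18 members and a median of −0.11 over 4 shared loci (percentile 13.1), which was 0.21 by the highest bin (81.3) and still −0.11 at matched length (3.36). The nesprin genes SYNE1 and SYNE2 had 8.94 and 8.30, and 6.22 and 5.34, with the SYNE2 locus upstream of the gene. LEMD3, an inner nuclear membrane protein gene, had 3.50 and 4.61.

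Long neuronal genes and imprinted genes were widely marked, again with close values in both libraries. A region was present at 88.1% and 51.9% of members, against 30.0% of all protein-coding genes, but these shares were not matched on gene length. Neuronal adhesion and synapse genes had a region at 37 of 42 members and a median of 0.06 over 179 shared loci (percentile 85.8), which was 0.04 (percentile 20.9) at loci of matched length and 0.07 (51.8) by the highest bin. PTPRN2, a receptor-type phosphatase of secretory vesicles, had 27 shared loci with a mean signal of 10.1 in control and 10.5 after CXCL12. CNTNAP2 had 8.01 and 8.38, SORCS2 7.98 and 7.62 (highest bins of 46 and 57), and DPP10 7.22 and 8.17. Imprinted genes had a region at 14 of 27 protein-coding members and a median of 0.06 over 49 shared loci (percentile 68.3), which was 0.13 by the highest bin (81.9). SNRPN, in the Prader-Willi region, had 23 shared loci with 16.5 and 17, the non-coding RNA gene MEG3 had 15.9 and 16.2, and ZNF331 had 12 and 12.2. PHLDA2 had 13.2 and 9.79 (log2 ratio −0.43) upstream of the gene, with 5800 bp called in control and 9200 bp after CXCL12.

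**Figure D4:**
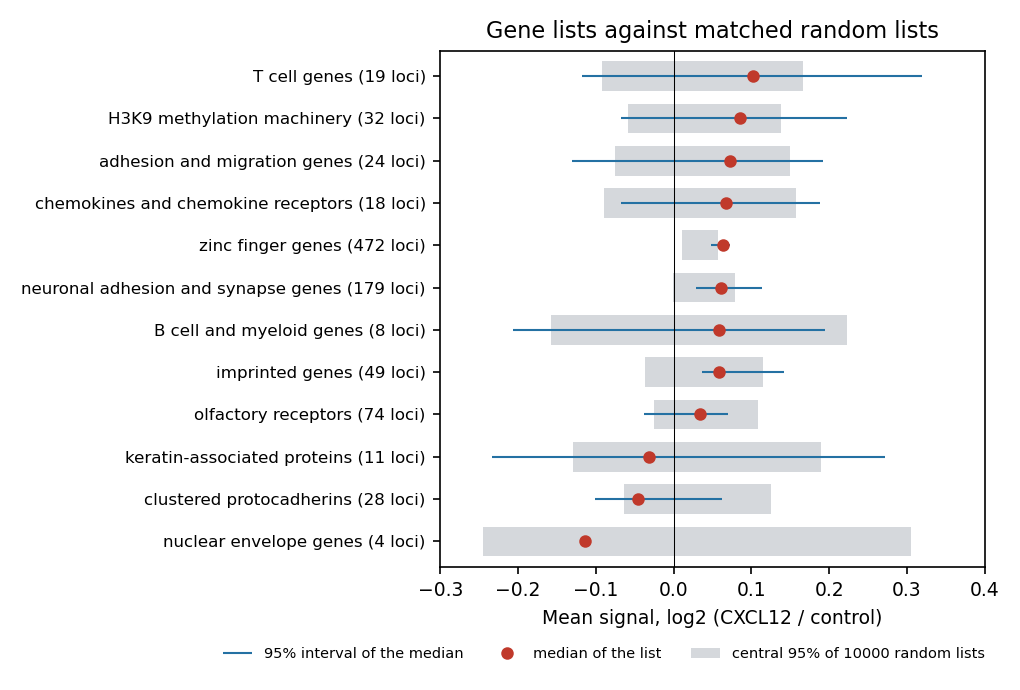
Median log2 ratio of mean signal, CXCL12 over control (red points), of the shared loci of each gene list, with its 95% interval over loci (blue lines, absent for the 4 nuclear envelope loci) and the central 95% of 10000 random lists matched on signal (grey bars). Of the 12 lists, only the point of the zinc finger genes, at 0.063, lies outside its grey bar.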

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

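The alternatives with lengths matched within 1.2-fold, with summed signal and with regions of at least 5 kb were chosen after seeing the data. More DNA was called after CXCL12 in each alternative run for it, with a ratio of 1.12 for regions of at least 5 kb (10272 regions in control, 11403 after CXCL12). Keeping regions at or above the median signal left 13356 and 13702 regions. The overlap, as a share of control and CXCL12 regions, was 82.8% and 78.1% when at least 50% of a region had to be shared, 81.3% and 78.2% at or above the median signal, and 82.6% and 73.6% for regions of at least 5 kb. Loci higher and lower by size numbered 491 and 413 with a 1.5-fold rule, 150 and 60 by the highest bin, 612 and 215 by summed signal, 9 and 14 with a pseudocount of 1, and 15 and 28 at or above the median signal, 21 and 44 when centred on the median, and 0 and 0 at matched lengths, a selection that removes loci whose lengths differ and in which the highest bin gave 53 and 14. The median log2 ratio was 0.034 at or above the median signal, 0.074 by the highest bin, 0.046 weighted by length and 0.062 at matched lengths. The zinc finger list went to percentile 93.7 with random lists matched on length, 34.6 by the highest bin and 91.4 at matched lengths, and the protocadherins to 2.40 by the highest bin. With the nearest gene alone 12 of 12 lists stayed inside or outside the central 95% of random lists as before, although the adhesion and migration list moved from percentile 72.6 to 44.4. As shares of covered length, gene bodies took 35.2% in control and 34.9% after CXCL12, gene-free regions 49.96% and 50.4%, and promoters 15.5% and 15.3%. Of 92 values of named loci and genes, 36 moved by at least 1 SD of the log2 ratio with the highest bin and 1 did with a pseudocount of 1. The sign was opposite for 25 of them with the highest bin, most of them small values, and for 6 when centred on the median. With the highest bin, NNT was the only value at least 2-fold apart to change direction, to 0.17. With the summed signal the direction was opposite at 10 of the 12 named loci with the largest ratios and 8 of the 12 with the smallest. Except where fewer regions or a lower threshold set the count, the cause was not tested. Leaving out a library was not possible with 1 per group, and leaving out loci of a single library gives no separate ratio. No paired analysis was possible because each group has 1 library and nothing was tested. The unknown depth limits what the weak loci show.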

Other observations

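The tests on loci at least 2-fold apart (the shuffling of lengths included), on depth or scaling, and on higher H3K9me3 as a cause of the longer regions were chosen after the results were seen, as were the named loci of matched length. The longest domains differed little between the libraries. Of 111 shared loci of at least 50 kb, 70 held a zinc finger gene and 58 lay on chromosome 19, and their log2 signal ratios ran from −0.15 to 0.21 with a median of 0.04. A 353.6 kb domain at the end of chromosome 12 (133418400 to 133773799), from CHFR to ZNF268, had a mean signal of 15.6 in control and 16.2 after CXCL12. A domain of 230.2 kb at chromosome 19, 54016800 to 54249599, covered ZNF331 and a cluster of placental microRNAs, with 12.1 and 12.2. Domains without zinc finger genes included 122.4 kb within SDK1, a synaptic adhesion gene (15.2 and 15.1), 107.6 kb at BAGE3 and BAGE on chromosome 21 (23.9 and 23.7), 101.8 kb at LARGE (7.21 and 7.32) and 100.2 kb over the SNORD116 repeats of SNRPN (25.8 and 28.5). Some domains were split differently: ZNF486 had 7 control regions and 1 CXCL12 region, ZNF91 had 6 and 1, and the ZNF732 to ZNF721 domain on chromosome 4 had 3 and 7. At these 3 the log2 ratios were −0.07, 0.02 and 0.05.

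Among loci of matched length that carry a gene and lie at or above the median signal, a selection that removes loci whose called lengths differ, the widest differences in mean signal were below 2-fold and again fell on unrelated genes. The highest were upstream of PRR23C, with a mean signal of 5.45 in control and 9.13 after CXCL12 (log2 ratio 0.74), and within TMPRSS12 (0.72) and RERE (0.72), a transcriptional corepressor gene whose highest bin was 13 in control and 26 after CXCL12. TUBB4Q (0.64), the insulin receptor gene INSR (0.59), FPR3 (0.59), DDX11L9 (0.57) and ZNF772 (0.56) followed. The lowest were within DTD1, with 10.8 and 7.16 (−0.60), and at ZNF404 (−0.55), the homeobox gene IRX2 (−0.53), AUH (−0.50), SPRR2G (−0.49), GPR161 (−0.48), POLR3B (−0.47) and within CXCL13 (−0.46), the chemokine gene, at chromosome 4, 78488000 to 78494199. By the highest bin, the log2 ratios of the 8 highest ran from 0.09 at TMPRSS12 to 1 at RERE. Those of the 8 lowest ran from −0.70 to −0.13. At least 1.5-fold differences in mean signal at matched length numbered 72 higher and 14 lower. Loci called in a single library with a signal at or above the median of shared loci numbered 617 in control and 510 after CXCL12.

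The loci at least 2-fold apart in mean signal, such as FUT8 and SLC27A2, may owe their ratio to the length called. The region was shorter in the library with the higher mean in 61 of 63 (96.8%, exact interval 89.0 to 99.6%). A mean divides by the called bins, so a part of this share is built in. Shuffling the lengths between loci gave 91.1%. The shuffle breaks the tie between length and summed signal, so it does not measure the built-in part in the data. This count therefore leaves the explanation open. By the highest bin, the median log2 ratio in the direction of the mean was 0.53 (0.45 to 0.74), short of 2-fold. Of the 63 loci, 11 did reach 2-fold there, NUBPL and ZNF254 among them. The highest bin is a maximum over the called region, which was longer in the library with the lower mean at nearly all of these loci. That can lower its ratio by construction, so it cannot settle whether signal differed 2-fold across these loci.

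The 10.0 Mb more DNA called after CXCL12 did not come mainly from the joining of regions called separately in control. Loci with unequal numbers of regions gained a net 1.33 Mb (1.75 Mb at joined and −0.42 Mb at split loci). Loci with equal numbers gained 5.99 Mb and loci of a single library 2.70 Mb. A region that grew over windows not called in control counts among the equal numbers, so joining of that kind was not tested. A difference in depth or scaling is a candidate explanation: at loci of matched length the median log2 ratio was above 0 in every quartile of summed signal, and the medians of the quartiles differed by only 0.011. Matching on called length is a selection tied to the signal ratio, so these medians cannot settle whether depth or scaling was the cause. In proportion, the gain in covered length was larger at weak loci, with 8.87% in the lowest quartile of mean signal and 3.07% in the highest. Higher H3K9me3 after CXCL12 cannot be told apart from this, because the median log2 ratio of 0.062 at matched length has no replicate spread to be set against.

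By the mean signal, but not by the highest bin (0.09 against 0.07 elsewhere), chromosome X had the lowest median log2 ratio, 0.004 over 831 loci against 0.04 on the other chromosomes. The summed signal went the other way, with a median log2 ratio of 0.137 on chromosome X and 0.114 elsewhere. For covered length the medians were 0.115 and 0.070. The lower signal level of chromosome X alone does not account for its low ratio of mean signal. The X median lay at percentile 0 of 10000 random locus sets matched on signal (central range 0.02 to 0.06). Among sets matched on covered length alone it lay at percentile 0.555. Chromosome X was picked as the lowest of the 23 chromosomes listed, which favours a low percentile, and signal and length were not matched together. Whether shorter covered length, alone or with lower signal, accounts for the low ratio therefore stays open. Lengths that differ more between the libraries may also account for the low ratio. Among loci of matched length, the 300 on chromosome X had a median of 0.06, at percentile 29.3 (central range 0.04 to 0.09). That selection is itself tied to the signal ratio, so it cannot settle the cause. No biological explanation was tested for chromosome X.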
